A study of Schizosaccharomyces pombe with 32 samples.

How the data were processed

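The series measured transcript levels in the fission yeast Schizosaccharomyces pombe on 32 spotted 2-colour arrays. Per the labels, each array carried polyA RNA of nitrogen-starved cells in Cy5 and polyA RNA of growing cells of the same strain in Cy3. Cells grew in a rich medium, were washed into a minimal medium without a nitrogen source, and were collected every hour from 1 to 8 h. The 16 arrays without pheromone used the strain labelled L972, and the 16 arrays with 0.5 ug per ml of synthetic P-factor used the strain labelled CRL672. Strain and pheromone therefore changed together and cannot be told apart. Each hour of each condition had 2 arrays. The array numbers in the labels fall into 4 consecutive or nearly consecutive series of 8 arrays, 1 for each condition and replicate, named here replicate 1 and replicate 2 of either condition. The labels do not number the replicates, so setting replicate 1 of one condition beside replicate 1 of the other was a choice. The replicate 2 series of both conditions had adjoining array numbers, and the replicate 1 series did not. The labels state that the experiments were repeated in each condition. The p-values rest on the spread over all arrays, with a correlation within a series shared by all genes. They do not measure the spread between the 2 repeats of a condition alone.

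The deposited values were taken as log2 ratios of starved over growing cells, 1 value for each probe and array. The direction came from the dyes in the labels. The log base is not given in the sources used here. The range of the values ruled out base 10, and base 2 was taken as the convention for such arrays, so a natural logarithm is not excluded and would change the size of every fold printed here. The authors' background and normalization steps are also not given. The arrays give no depth, and their number limits the precision. No dye swap was labelled, so a dye bias of a gene stays in its ratio against growing cells.

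Of the 5188 probes, 4868 matched 1 gene, 22 matched several and 298 were not listed in the gene table for the array. The values of probes for the same gene were averaged, which concerned 4 of the 4819 genes. Each array was centred on the median over all its genes, after this averaging, and its probes without a single gene, which lay between -0.154 and 0.091. Genes measured on at least 24 of the 32 arrays were tested, 4811 in all. The share of missing values was 0.456%.

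A linear model with a mean for each of the 16 groups was fitted with limma 3.58.1 in R 4.3.3. The array series entered as a random block, with a consensus correlation of 0.354, and the spread of each gene was moderated over all genes (16 residual and 6.32 prior degrees of freedom). The contrasts were the average of 1 to 8 h against growth in each condition, each hour against growth, the mean of 6, 7 and 8 h minus the mean of 1, 2 and 3 h in each condition (late minus early), the P-factor condition minus the condition without it for the average and for each hour, and the difference of the late minus early changes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with 0.05 as the threshold. Every ± is a standard error of the model. The fit was tested on simulated data: 100 genes were changed by 1 and 100 by 2 on the log2 scale in each of 3 comparisons at once, among 4811 genes. Of the genes changed by 1, it recovered 89% for the averaged P-factor difference and 81% for the difference of late minus early changes. Of 400 and 363 calls in all, which include genes changed for the other comparisons, 37 and 10 fell on unchanged genes. For the averaged difference this share was above the threshold of 0.05. The simulated noise had the same correlation within a series for every gene, as the model assumes. It could not show errors from series effects that differ between genes.

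For groups of genes, 21 lists were tested with the pre-ranked form of camera in limma at a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. Camera with an estimated correlation and no block, and fry with the block, stood beside it. Where only one adjusted p is given for a list, it is camera's at the preset correlation. The subtelomeric list held genes within 100 kb of a chromosome end in assembly ASM294v3, which served for names and neighbours alone. The list of cytosolic ribosomal proteins was built from name patterns and so took in rpp1 and rpp40, subunits of RNase P.

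The comparisons, their tests, the lists and the rule for naming genes were set before the data were examined. The rule named 17 measured genes of mating, meiosis, telomeres and nitrogen starvation in every comparison. To these it added the 8 called genes with the largest change in each direction among those with the same sign in both array series, and up to 4 called members of each list. A gene named outside this rule is said to have been chosen after its values were seen.

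Alternatives were the values without centring, arrays scaled to a common spread, other filters on missing values, no block, a fixed block, series means, a robust spread with trend, a linear trend over time, a threshold on size, fits within the replicate 1 arrays and within the replicate 2 arrays, and fits without each array or each array series. Another 3 settings were added after the data were seen, namely all probes, genes away from the level of probes without a single gene, and centring on genes outside the ribosomal protein list. map2, which encodes the P-factor precursor, had no measured probe.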

Results

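Fission yeast leaves the mitotic cycle when nitrogen runs out, and cells of 1 mating type then respond to the peptide pheromone of the other. P-factor is the pheromone of P cells, which M cells sense. The series followed transcript levels for 8 h after nitrogen removal, with and without synthetic P-factor, on 32 arrays in 16 groups of 2. Each value is a log2 ratio of starved over growing cells of the same strain, and 4811 genes were tested. The 2 arrays of an hour correlated over genes at 0.84 to 0.901 without P-factor and at 0.865 to 0.943 with it, where genes are not independent replicates. The first principal component held 32% of the variance and the second 21%. On the second, the arrays of replicate 1 without P-factor lay between 8.16 and 33.97, those of replicate 2 between -11.44 and 7.83, and the P-factor arrays between -18.28 and -5.32.

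The first comparison asked which transcripts differed between starved and growing cells without pheromone, averaged over 1 to 8 h (16 arrays). Genes for taking up and recycling nitrogen stood far above growth. The protease gene isp6 (SPAC4A8.04) was 70.6-fold higher (6.14 ± 0.13, adjusted p = 5.18e-20), and the permease genes isp5, put4 and isp4, for amino acids, proline and oligopeptides, stood at 6.36 ± 0.32, 5.35 ± 0.23 and 4.95 ± 0.21. All 25 autophagy genes were higher, with a median of 1.47 (adjusted p = 7.21e-13). Genes for making ribosomes were lower. Of 123 cytosolic ribosomal protein genes, 119 were lower and 2 higher, with a median of -2.09 (adjusted p = 1.63e-44, and adjusted p = 0.127 with an estimated correlation). Of 40 ribosome biogenesis genes, 37 were lower and 1 higher, with a median of -1.59 (adjusted p = 1.07e-16), led by the RNA helicase gene dbp3 at -3.17 ± 0.12.

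Among the other lists in cells without pheromone, 15 of 19 genes of nitrogen uptake were higher and 2 lower (median 1.94, adjusted p = 2.55e-10, and adjusted p = 0.116 with an estimated correlation). Of 22 core stress genes, 19 were higher and 1 lower (median 2.07, adjusted p = 1.21e-05, and adjusted p = 0.122 with an estimated correlation), led by the metallothionein gene zym1 at 5.75 ± 0.35 and followed by hsp9 at 4.09 ± 0.28 and the catalase gene ctt1 at 3.15 ± 0.36. Respiration genes were higher in 32 of 35 cases (median 0.87, adjusted p = 5.12e-07, and adjusted p = 0.0699 with an estimated correlation), such as the malate dehydrogenase gene mdh1 at 2.24 ± 0.14. Chaperone genes of the protein folding list were lower in 18 of 22 cases and higher in 1 (median -1.20, adjusted p = 6.64e-05, and adjusted p = 0.0699 with an estimated correlation), such as mas5 at -2.00 ± 0.16. Of 49 amino acid biosynthesis genes, 33 were lower and 9 higher (median -0.57, adjusted p = 0.00123, and adjusted p = 0.358 with an estimated correlation). Subtelomeric genes were higher in 57 of 99 cases and lower in 9 (median 0.62, adjusted p = 3.33e-05, and adjusted p = 0.0699 with an estimated correlation). They held hhy1 at 6.76 ± 0.33, SPAC869.04 at 7.10 ± 0.66 and SPAC869.03C at 6.41 ± 0.31, all among the 8 largest increases. The remaining ones of these 8 were SPBC800.11 at 6.08 ± 0.20 and urg1, a gene of uracil breakdown, at 6.07 ± 0.25. The largest decreases were SPAC8E11.10 at -4.47 ± 0.28 and SPAPB24D3.07C at -4.20 ± 0.26, followed by the adenine deaminase gene dea2 at -3.28 ± 0.16, ani1 at -3.15 ± 0.14, rpl3002 at -3.10 ± 0.24, the La protein gene sla1 at -3.06 ± 0.14 and the adenine phosphoribosyltransferase gene apt1 at -3.02 ± 0.17.

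Mating genes were also higher without added pheromone. Of 28 mating and pheromone signalling genes, 19 were higher and 2 lower (median 1.26, adjusted p = 9.4e-05, and adjusted p = 0.0699 with an estimated correlation). Of 8 genes specific to M cells, 6 were higher (median 2.28, adjusted p = 0.00105, and adjusted p = 0.116 with an estimated correlation). The M-factor precursor gene mfm1 (SPAPB8E5.05) stood at 5.21 ± 0.35, the P-factor receptor gene mam2 (SPAC11H11.04) at 3.73 ± 0.32, and ste11 (SPBC32C12.02), the transcription factor that drives mating genes, at 1.94 ± 0.12. Of 13 meiotic regulators, 9 were higher (median 0.62, adjusted p = 0.0149, and adjusted p = 0.0699 with an estimated correlation), among them mei2 (SPAC27D7.03C), the RNA-binding inducer of meiosis, at 4.24 ± 0.36. The nuclear envelope gene kms1 (SPAC3A11.05C) was higher at 1.40 ± 0.14, as was fnx1 at 1.93 ± 0.16, while sad1 (SPBC12D12.01), a spindle pole body gene, was lower at -0.78 ± 0.16. Smaller calls were the telomere protein gene taz1 at 0.51 ± 0.13, the meiotic cohesin gene rec8 at 0.76 ± 0.29 and the meiotic transcription factor gene mei4 at 0.48 ± 0.18, and each of these 3 was lost without replicate 1. The bouquet genes bqt1 (SPAC6G9.13C) and bqt2 (SPAC1002.06C) stood at -0.04 ± 0.20 and 0.16 ± 0.16 and were not called (adjusted p = 0.866 and 0.407), nor were dhc1 at 0.22, sxa2 at 0.24, rap1 at 0.46 and fus1 at 1.25. Histone genes were higher in 9 of 10 cases (median 0.64, adjusted p = 0.0297, and adjusted p = 0.358 with an estimated correlation) and mitosis and septation genes in 13 of 25 (median 0.60, adjusted p = 0.0298, and adjusted p = 0.278 with an estimated correlation). The histone call was lost in 7 of 13 alternatives, the fits without each of the 4 series among them, and the mitosis call without either series of the P-factor condition. The lists of G1/S genes, glycolysis, proteasome, sporulation, recombination, P-cell genes and telomere and bouquet genes did not pass (adjusted p = 0.414, 0.464, 0.414, 0.321, 0.41, 0.883 and 0.414).

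In total 3319 genes differed from growth in limma at an adjusted p below 0.05, 1623 higher and 1696 lower, and 1396 of them by at least 2-fold. The calls of the autophagy and ribosome biogenesis lists held with an estimated correlation. Adjusted over the list alone, 120 ribosomal protein genes were lower, 34 amino acid genes were lower and 20 mating genes were higher, and the counts for autophagy, ribosome biogenesis, nitrogen uptake, stress and respiration did not move.

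With P-factor the question was the same, in the strain labelled CRL672. Starvation again raised isp6 (6.11 ± 0.13), SPAC869.04 (7.31 ± 0.66), urg1 (6.59 ± 0.26), hhy1 (6.25 ± 0.33), SPAC869.03C (6.13 ± 0.31) and isp4 (5.93 ± 0.21), and mating genes now stood among the 8 largest increases. The receptor gene mam2 was 68.5-fold higher (6.10 ± 0.32, adjusted p = 3.01e-13), and mfm1 stood at 6.41 ± 0.37. Of 28 mating genes, 25 were higher and 2 lower, with a median of 2.08 (adjusted p = 2.97e-10), a call that held with an estimated correlation. Of 20 recombination and chromosome axis genes, 14 were higher (median 1.03, adjusted p = 0.00573, and adjusted p = 0.12 with an estimated correlation, lost without genes near the level of probes without a single gene), such as rec8 (SPBC29A10.14) at 2.03 ± 0.29, the kinase gene mek1 at 2.02 ± 0.21 and the axis gene hop1 at 1.75 ± 0.24.

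Of the bouquet genes, bqt1 was higher at 1.34 ± 0.20 (adjusted p = 3.57e-06), and bqt2 was higher at 0.60 ± 0.16 (adjusted p = 0.00229, lost without replicate 2). The dynein heavy chain gene dhc1 (SPAC1093.06C) stood at 1.29 ± 0.17, its cortical anchor gene num1 at 2.00 ± 0.21, mei2 at 5.43 ± 0.36, ste11 at 2.08 ± 0.12, fus1 (SPAC20G4.02C), the formin gene of cell fusion, at 1.60 ± 0.57, mei4 (SPBC32H8.11) at 1.10 ± 0.18 and kms1 at 1.08 ± 0.14. The gene sxa2 (SPAC1296.03C), for the carboxypeptidase that breaks down P-factor, was lower at -0.36 ± 0.14 (adjusted p = 0.0251, lost without either replicate). On 11 of the 16 arrays with P-factor it lay near the median of probes without a single gene, so this size is uncertain. Of 20 telomere, bouquet and nuclear movement genes, 11 were higher and 2 lower, and the list did not pass (median 0.38, adjusted p = 0.0797). Ribosomal protein genes were lower in 121 of 123 cases (median -2.05, adjusted p = 3.53e-44, and adjusted p = 0.12 with an estimated correlation) and ribosome biogenesis genes in 37 of 40 (median -1.70, adjusted p = 8.45e-22). The largest decreases were SPAC8E11.10 at -4.01 ± 0.28, the ribosome assembly gene rrb1 at -3.85 ± 0.16, ani1 at -3.53 ± 0.14, sla1 at -3.39 ± 0.13, wis2 at -3.25 ± 0.33, dbp3 at -3.22 ± 0.12, srp40 at -3.15 ± 0.37 and ani2 at -3.14 ± 0.15. Autophagy genes were higher in 24 of 25 cases (median 1.33, adjusted p = 7.07e-12). In total 3209 genes were called, 1633 higher and 1576 lower, and 1372 by at least 2-fold. Adjusted over the list alone, the mating counts were 25 higher and 3 lower and the recombination count 14 higher. The conditions shared 1369 higher genes, where 550.9 would be shared if calls were independent, and 1407 lower ones, where 555.6 would be, with 11 genes called in opposite directions. The test over all 16 hourly groups called 3828 genes, and single hours called 2492 to 2833 genes without P-factor and 2416 to 2758 with it.

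The next comparison asked how transcripts moved between 1 to 3 h and 6 to 8 h without P-factor. The mating programme rose. The M-factor genes mfm1 and mfm3 rose by 7.04 ± 0.35 and 6.83 ± 0.43, mam2 by 4.78 ± 0.32, mei2 by 3.71 ± 0.36, the pheromone signalling regulator rgs1 by 2.36 ± 0.35, the M-factor transporter gene mam1 by 2.35 ± 0.20 and ste11 by 2.07 ± 0.12. Of 28 mating genes, 16 rose and 2 fell (median 0.86, adjusted p = 7.18e-10, and adjusted p = 0.0554 with an estimated correlation), and 6 of 8 M-cell genes rose (median 2.08, adjusted p = 8.4e-13). Genes for ribosomes rose again from their low early level, 115 of 123 ribosomal protein genes (median 0.80, adjusted p = 1.56e-23, and adjusted p = 0.151 with an estimated correlation) and 33 of 40 ribosome biogenesis genes with 1 that fell (median 0.90, adjusted p = 2.59e-17).

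All 10 histone genes fell over this time without P-factor (median -1.03, adjusted p = 1.25e-10), such as htb1 by -1.29 ± 0.13. Proteasome genes fell in 18 of 32 cases (median -0.29, adjusted p = 1.06e-05), such as pre9 by -0.82 ± 0.12. Of 26 G1/S and DNA replication genes, 13 fell and 1 rose (median -0.41, adjusted p = 0.00167, and adjusted p = 0.09 with an estimated correlation). Of 49 amino acid genes, 26 fell and 4 rose (median -0.42, adjusted p = 3.67e-06, and adjusted p = 0.313 with an estimated correlation), and of 25 mitosis and septation genes 12 fell and 3 rose (median -0.37, adjusted p = 0.00857, and adjusted p = 0.19 with an estimated correlation), such as the septum glucanase gene eng1 by -2.30 ± 0.30. Protein folding genes rose in 12 of 22 cases and fell in 1 (median 0.40, adjusted p = 0.00313, and adjusted p = 0.275 with an estimated correlation), such as ssa2 by 2.28 ± 0.20. The largest decreases were SPBPB10D8.02C at -3.49 ± 0.35, SPCC18B5.02C at -2.90 ± 0.43, gst2 at -2.63 ± 0.48, SPBC1271.08C at -2.62 ± 0.20, aat1 at -2.60 ± 0.18, SPCC70.08C at -2.45 ± 0.30, alr2 at -2.44 ± 0.34 and urg1 at -2.36 ± 0.25. The gene bqt1 moved by 0.36 ± 0.20 and was not called, and bqt2 fell by 0.40 (adjusted p = 0.0486, lost without replicate 1). In total 2034 genes were called, 1153 higher and 881 lower late, 361 by at least 2-fold. With the values as deposited the split was 982 higher and 1063 lower. The count was 1024 without replicate 1 and 1192 without replicate 2. Adjusted over the list alone, 14 G1/S genes, 19 proteasome genes and 27 amino acid genes fell, and 34 ribosome biogenesis genes rose. The histone, M-cell, proteasome and ribosome biogenesis calls held with an estimated correlation.

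With P-factor the late increase reached further into mating and meiosis. The cell fusion gene dni2 rose by 6.04 ± 0.31, the kinase gene shk2 by 5.63 ± 0.25, the agglutination gene mam3 by 5.33 ± 0.25, rgs1 by 4.94 ± 0.37 and mug8 by 4.84 ± 0.24, next to mfm3 (7.21 ± 0.43), mam2 (6.60 ± 0.32) and mfm1 (6.27 ± 0.38). The bouquet gene bqt1 rose by 3.02 ± 0.20 (adjusted p = 4.06e-11), num1 by 3.44 ± 0.21, dhc1 by 1.99 ± 0.17, rec8 by 3.39 ± 0.29, mek1 by 3.34 ± 0.21, mei2 by 4.59 ± 0.36, ste11 by 3.11 ± 0.12, mei4 by 1.48 ± 0.18 and kms1 by 1.40 ± 0.14. Of 28 mating genes 24 rose (median 2.70, adjusted p = 2.5e-29), of 8 M-cell genes 7 rose (median 4.51, adjusted p = 8.81e-18), of 20 recombination genes 16 rose and 2 fell (median 1.42, adjusted p = 4.14e-09), and of 20 telomere, bouquet and nuclear movement genes 16 rose (median 0.82, adjusted p = 5.67e-06). Smaller rises were called for taz1 (SPAC16A10.07C) at 0.63 ± 0.13 and bqt2 at 0.46 ± 0.16, and bqt2 was not called without either replicate or with the values as deposited. The gene fus1 rose by 2.08 ± 0.57 (adjusted p = 0.00364, lost without replicate 2). Its replicate 1 read 3.99 at 6 h and -0.30 and -0.55 at 7 and 8 h, where replicate 2 read 4.27 and 3.61. In replicate 1 the median of probes without a single gene was -0.23 and -0.41 at 7 and 8 h. The low fus1 values there were thus not told apart from an empty spot.

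Subtelomeric genes fell in 76 of 99 cases and rose in 3 over this time with P-factor (median -0.75, adjusted p = 3.77e-15), led by SPAC869.01 at -3.68 ± 0.42 and SPAC186.06 at -3.38 ± 0.22. Of 319 probes without a single gene, 62.4% were lower and 11% higher in the same comparison. Ribosome biogenesis genes rose in 32 of 40 cases and fell in 1 (median 0.96, adjusted p = 8.12e-09), whereas of the ribosomal protein genes 6 rose and 5 fell, and that list did not pass (median 0.00, adjusted p = 0.175). Its median was -0.20 in replicate 1 and 0.20 in replicate 2, and it passed as lower without replicate 2 and with scaled arrays. Protein folding genes rose in 17 of 22 cases (median 0.51, adjusted p = 0.000733, and adjusted p = 0.142 with an estimated correlation). Amino acid genes fell in 32 of 49 cases and rose in 6 (median -0.56, adjusted p = 1.03e-08, and adjusted p = 0.212 with an estimated correlation), and histone genes fell in 9 of 10 cases and rose in 1 (median -1.24, adjusted p = 3.77e-09, and adjusted p = 0.0543 with an estimated correlation). Other large decreases were SPAC11D3.01C at -3.39 ± 0.54, the uridine hydrolase gene urh1 at -3.20 ± 0.18, alr2 at -3.11 ± 0.34, dgc1 at -3.09 ± 0.26, urg1 at -2.93 ± 0.26 and SPBC1271.07C at -2.89 ± 0.20. In total 2576 genes were called, 1623 higher and 953 lower late, 623 by at least 2-fold. With the values as deposited the split was 1125 higher and 1480 lower, and in the centred values the median over all genes was 0.11. Adjusted over the list alone, 79 subtelomeric genes fell and 17 telomere, bouquet and nuclear movement genes rose. The mating, M-cell, recombination, telomere and bouquet, ribosome biogenesis and subtelomeric calls held with an estimated correlation.

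The P-factor condition minus the condition without it asked what pheromone and strain changed together. Averaged over 1 to 8 h, mating and fusion genes led the increases. The kinase gene shk2 (SPAC1F5.09C) was 9.63-fold higher (3.27 ± 0.36, adjusted p = 9.94e-06), followed by dni2 at 3.14 ± 0.43, mam3 at 2.61 ± 0.35, dni1 at 2.37 ± 0.33, mam2 at 2.37 ± 0.46, mug14 at 2.23 ± 0.44, rlp24 at 2.18 ± 0.43 and rgs1 at 2.11 ± 0.51. The sizes and ranks of dni1, dni2 and rlp24 are uncertain, since they lay near the median of probes without a single gene, dni1 and dni2 on 16 and 12 of the 16 arrays without P-factor and rlp24 on 13 of the 16 with it. The gene bqt1 was higher at 1.38 ± 0.28 (adjusted p = 0.00741), and dhc1 at 1.07 ± 0.25 (adjusted p = 0.0159). Of 28 mating genes 7 were higher (median 0.65, adjusted p = 2e-11), of 20 recombination genes 6 (median 0.69, adjusted p = 2.29e-07), of 8 M-cell genes 3 (median 1.07, adjusted p = 4.07e-06), and of 26 G1/S genes 4 were higher and 1 lower (median 0.38, adjusted p = 3.9e-07). These calls held narrowly in camera with an estimated correlation and no block. The adjusted p was 0.0296 for mating genes and 0.0484 for each of the recombination, M-cell and G1/S lists. The calls of the recombination and M-cell lists were lost within the replicate 1 arrays. The telomere and bouquet list had 3 higher genes (median 0.17, adjusted p = 0.00924, and adjusted p = 0.169 with an estimated correlation). Its call was lost within the replicate 1 arrays, without replicate 2 of the condition without P-factor, and without genes near the level of probes without a single gene. The stress list (median -0.62, adjusted p = 0.000672) had no called gene, and adjusted p = 0.212 with an estimated correlation.

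The decreases of this average were led by nrg1 (SPBPB2B2.01) at -4.66 ± 0.19 (adjusted p = 7.22e-14), SPBPB2B2.05 at -4.04 ± 0.55, isp7, an oxygenase gene of the nitrogen starvation response, at -3.39 ± 0.88, SPBC8E4.03 at -2.58 ± 0.26, SPBPB2B2.06C at -2.52 ± 0.62, prt2 at -2.31 ± 0.41, srp40 at -1.98 ± 0.52 and fah2 at -1.70 ± 0.45. On the P-factor arrays nrg1, SPBPB2B2.05 and SPBC8E4.03 lay near the median of probes without a single gene on 16, 15 and 16 of 16 arrays, so the sizes and ranks of their differences are uncertain. The gene nrg1 stood at 4.63 ± 0.14 over growth without P-factor and at -0.03 ± 0.14 with it. The call of isp7 rested on replicate 1 without P-factor. The difference was -5.94 within the replicate 1 arrays and -0.58 within the replicate 2 arrays. The subtelomeric list had 8 lower and 2 higher genes (median -0.16, adjusted p = 0.000721, and adjusted p = 0.208 with an estimated correlation). In total limma called 160 genes, 102 higher and 58 lower, 78 by at least 2-fold, and 785 genes had an unadjusted p below 0.05. Adjusted over the list alone, 13 mating genes were higher and 1 lower, and 11 recombination genes and 9 G1/S genes were higher. The split was 146 higher and 148 lower without replicate 1 of the condition without P-factor, and 258 higher and 511 lower within the replicate 2 arrays. Over all genes the averaged difference correlated at 0.378 between the replicate 1 and the replicate 2 arrays. The count was 294 and 1194 without replicate 1 and replicate 2 of the condition without P-factor, and 20 and 24 without replicate 1 and replicate 2 of the P-factor condition. Without replicate 1 of the P-factor condition, bqt1, dhc1 and mam2 were not called, and 22 of the 32 called genes among those named by the rule were lost without 1 of the 4 series.

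The difference grew with time. At 1 h 8 genes were called, at 2 h 3, at 3 h 1 and at 4 h 5, whereas 48 were called at 5 h, 210 at 6 h, 346 at 7 h and 428 at 8 h, 306 of the last higher and 122 lower. The genes called at 2 to 4 h were nrg1, SPBC8E4.03, SPBPB2B2.05, rlp24, pfl5 and SPBC8E4.04, and the last pair was chosen after the values were seen. The agglutination gene mam3 differed by 1.43 at 4 h (adjusted p = 0.687) and by 4.94 at 5 h (adjusted p = 6.44e-06). The bouquet gene bqt1 differed by -0.12 at 4 h (adjusted p = 0.983), by 2.39 at 5 h (adjusted p = 0.00418) and by 3.22 at 8 h (adjusted p = 3.94e-05), with 3.71 and 2.90 on the P-factor arrays at 8 h and 0.23 and -0.05 on the others. The gene bqt2 differed by 0.99 at 7 h (adjusted p = 0.0925) and by 1.92 at 8 h (adjusted p = 0.000899), with 1.61 and 1.99 on the P-factor arrays and -0.42 and 0.20 on the others. A test over the 8 hours together called 355 genes. That count was 118 without replicate 1 of the condition without P-factor, 177 without replicate 1 of the P-factor condition and fewer without its replicate 2. The hourly counts moved with the series as well. Without replicate 2 of the condition without P-factor they were 45, 46, 66 and 72 at 1 to 4 h, 3.15 times the reported count at 5 h, and 369, 422 and 604 at 6 to 8 h. The lowest counts without a series were 10, 37 and 89 at 5 to 7 h and 0.308 of the reported count at 8 h, each without a series of the P-factor condition. With 1 array left out, the counts were 4 to 28 at 1 h, 1 to 6 at 2 h, 1 to 2 at 3 h and 2 to 6 at 4 h, and at 5 h they were 12 without replicate 1 and 73 without replicate 2 of the P-factor arrays of that hour. Leaving out replicate 1 of the P-factor arrays at 6 h left 70 genes at that hour, and leaving out replicate 2 at 7 and 8 h left 171 and 218.

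**Figure D1:**
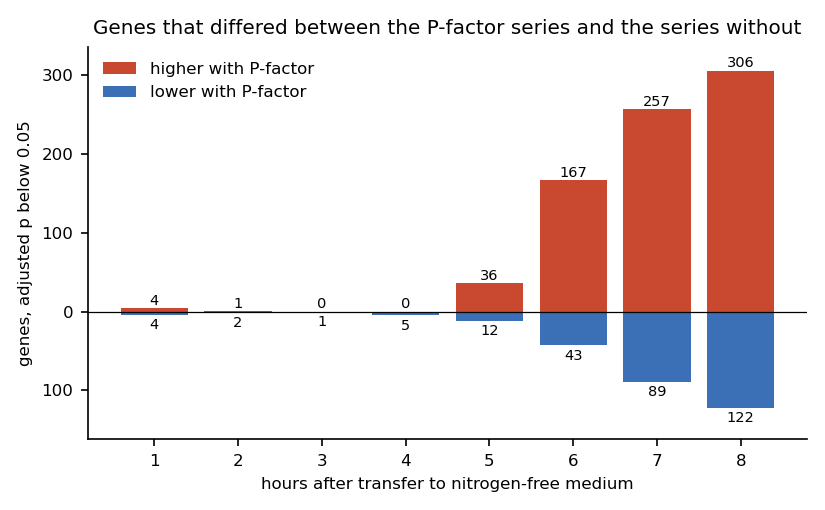
Number of genes with an adjusted p below 0.05 in the P-factor condition minus the condition without it, at each hour after nitrogen removal (limma, 2 arrays in each group), with higher genes above and lower genes below the axis. The counts were at most 8 up to 4 h and reached 306 higher and 122 lower at 8 h.

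**Figure D2:**
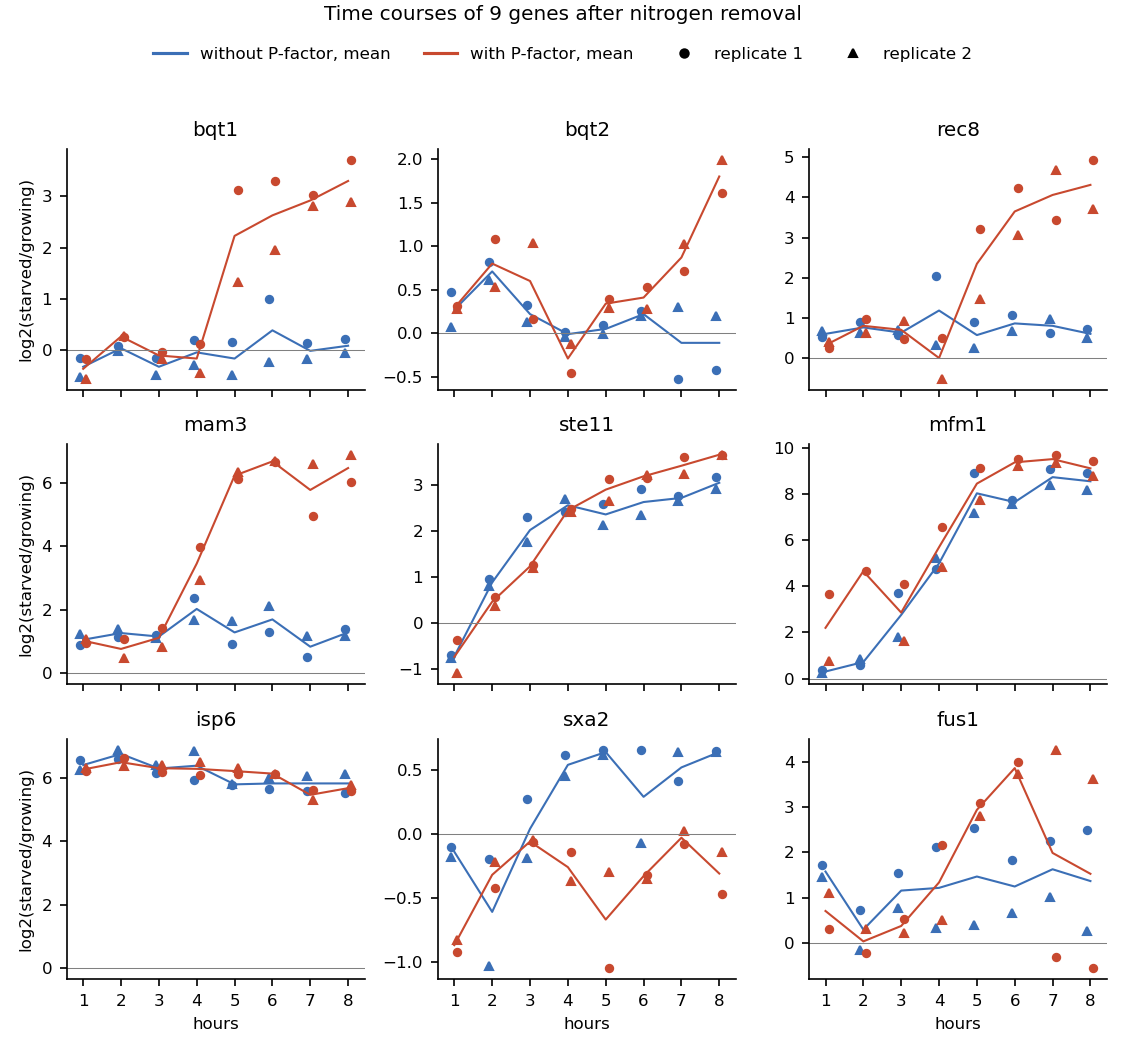
Log2 ratios of starved over growing cells for 9 genes against hours after nitrogen removal, with a point for each array and a line for the mean of the 2 arrays of an hour. At 8 h bqt1 read 3.71 and 2.90 with P-factor and 0.23 and -0.05 without, and bqt2 read 1.61 and 1.99 with P-factor.

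The last comparison asked which late minus early changes differed between the conditions. Genes of mating and meiosis were prominent among the higher late changes with P-factor. The change of shk2 was higher by 5.49 ± 0.36 (adjusted p = 6.15e-10), that of mam3 (SPAP11E10.02C) by 5.22 ± 0.35, of dni2 (SPBC4.01) by 5.04 ± 0.43, of dni1 (SPAC31G5.07) by 4.73 ± 0.33, of mug14 by 4.08 ± 0.44, of the chromosome pairing gene meu13 by 3.88 ± 0.36, of mug8 by 3.44 ± 0.35 and of the cyclin gene cig2 by 3.30 ± 0.34. Of 28 mating genes 19 had a higher late change and 1 a lower one, with a median of 1.18 (adjusted p = 6.8e-14). They included tht1, for the fusion of nuclei, at 2.60 ± 0.28. Of the M-cell genes, 5 of 8 had a higher change and 1 a lower one (median 1.53, adjusted p = 0.000576, and adjusted p = 0.0567 with an estimated correlation), among them the mating-type genes mat1-Mc at 1.87 ± 0.30 and mat1-Mi at 1.94 ± 0.34.

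The telomere, bouquet and nuclear movement genes had a higher late change in 12 of 20 cases (median 0.59, adjusted p = 8.16e-06). They included bqt1 at 2.66 ± 0.28 (adjusted p = 5.98e-07), num1 at 3.26 ± 0.30 and dhc1 at 1.69 ± 0.25 (adjusted p = 3.38e-05). The change of bqt2 was higher by 0.86 ± 0.23 (adjusted p = 0.00735) and was 0.50 and not called without replicate 1 of the condition without P-factor. That of kms1 was higher by 0.89 ± 0.20 (adjusted p = 0.00249, lost without replicate 2 of the P-factor condition), while taz1 at 0.35, rap1 (SPBC1778.02) at 0.45 and sad1 at -0.02 were not called. Recombination genes had a higher change in 14 of 20 cases (median 1.26, adjusted p = 1.25e-09), among them rec8 at 3.30 ± 0.41, hop1 at 2.82 ± 0.34 and mek1 at 2.75 ± 0.30. G1/S and DNA replication genes had a higher change in 18 of 26 cases and a lower one in 1 (median 0.78, adjusted p = 6.43e-09), among them the kinase gene mik1 at 2.71 ± 0.29 and cdt2, an adaptor of a ubiquitin ligase, at 2.19 ± 0.22.

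Of 13 meiotic regulators 5 had a higher change and 1 a lower one, such as the transcription factor gene rep1 at 2.28 ± 0.26, the cyclin gene crs1 at 2.30 ± 0.35 and pat1, the kinase that holds meiosis back, at 2.13 ± 0.25. That list did not pass (adjusted p = 0.118), and its median was -0.04 with a mean of 0.53. The change of ste11 was higher by 1.03 ± 0.17 (adjusted p = 0.000178), of mam2 by 1.83 ± 0.46 and of mei4 by 0.88 ± 0.25. The call of mam2 was lost without replicate 1 of the condition without P-factor and without replicate 2 of the P-factor condition, where its lowest value was 0.99. That of mei4 was lost without these and without replicate 2 of the condition without P-factor, where its lowest value was 0.66. The late change of sxa2 was lower at -0.53 ± 0.19 (adjusted p = 0.046), a call that no fit without an array series kept. This gene lay near the median of probes without a single gene on 11 of 16 arrays with P-factor and 8 of 16 without. The size of its difference is therefore uncertain. The differences of mei2 (0.88), mfm1 (-0.77), fus1 (1.68), isp6 (0.06) and fnx1 (-0.28) were not called. Without P-factor several of the genes above lay within 0.5 of the median of probes without a single gene, where signal was not told apart from an empty spot, so the sizes and ranks of their differences are uncertain. These were dni1 and crs1 on all 16 arrays, bqt1 and dhc1 on 15, bqt2, num1 and mat1-Mi on 14, hop1 on 13 and dni2 on 12. The median of probes without a single gene is not a measured background. Of 319 such probes, 33.5% were called against growth without P-factor, and an unchanged gene with signal can lie near this median as well.

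Lower late changes with P-factor were led by rlp24, a ribosome biogenesis gene, at -2.68 ± 0.42 (adjusted p = 8.26e-05), SPAPB1A11.03 at -2.26 ± 0.70, SPAC869.01 at -2.25 ± 0.60, hsp3105 at -2.14 ± 0.38, SPAC186.02C at -2.10 ± 0.48, SPAC11D3.01C at -2.08 ± 0.77, hry1 at -1.99 ± 0.44 and dak2, a dihydroxyacetone kinase gene, at -1.92 ± 0.56. With P-factor rlp24 lay near the median of probes without a single gene on 13 of 16 arrays, so the size of its difference is not that of a spot shown to give signal. SPAPB1A11.03, SPAC11D3.01C, SPAC869.01, hry1 and dak2 were each lost without 1 or more of the 4 series. Cytosolic ribosomal protein genes had a lower late change in 109 of 123 cases and a higher one in none (median -0.79, adjusted p = 2.03e-30, and adjusted p = 0.106 with an estimated correlation), such as rps2201 at -1.51 ± 0.25 and rps2202 at -1.32 ± 0.21. Their median over growth at 8 h was -1.50 and -1.45 without P-factor and -1.92 and -1.94 with it, and at 1 h it was -2.26 and -2.55 against -1.61 and -2.15. Subtelomeric genes had a lower late change in 42 of 99 cases and a higher one in 2 (median -0.63, adjusted p = 3.54e-11), and the median of probes without a single gene also moved down late on the P-factor arrays, with 49.8% of 319 such probes lower and 3.8% higher in this comparison.

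Proteasome genes, of which 18 fell late without P-factor and 4 with it, had a higher late change in 8 of 32 cases (median 0.29, adjusted p = 0.0103, and adjusted p = 0.171 with an estimated correlation), such as pup3 at 0.79 ± 0.17, lost without replicate 2 of the P-factor condition. Nitrogen uptake genes had a lower change in 4 of 19 cases (median -0.48, adjusted p = 0.0164, and adjusted p = 0.338 with an estimated correlation), such as put4 at -1.21 ± 0.33, which held only without replicate 2 of the P-factor condition among the fits without a series. Amino acid genes had a lower change in 9 of 49 cases and a higher one in 5 (median -0.18, adjusted p = 0.0262, and adjusted p = 0.668 with an estimated correlation), such as lys9 at -1.10 ± 0.24 and ser3 at 1.86 ± 0.35. Glycolysis genes had a lower change in 2 of 23 cases and a higher one in 1 (median -0.41, adjusted p = 0.0326, and adjusted p = 0.478 with an estimated correlation), such as pyk1 at -0.98 ± 0.24, lost without replicate 2 of the condition without P-factor and without replicate 1 of the P-factor condition. Of the 3 measured P-cell genes, map3, the M-factor receptor gene, at 1.41 ± 0.26 and map4 had a higher change, and the list did not pass (adjusted p = 0.0758). Autophagy, histone, mitosis, stress, folding, respiration, ribosome biogenesis and sporulation genes did not pass as lists (adjusted p = 0.722, 0.369, 0.719, 0.202, 0.276, 0.967, 0.369 and 0.722).

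In total limma called 1241 genes in the difference of late minus early changes, 752 higher and 489 lower, 376 by at least 2-fold. With the values as deposited the split was 549 higher and 694 lower. Over all genes the difference correlated at 0.712 between the replicate 1 and the replicate 2 arrays. The count was 562 and 668 without replicate 1 and replicate 2 of the condition without P-factor, and 785 without replicate 1 of the P-factor condition. Adjusted over the list alone, 20 mating genes and 19 G1/S genes had a higher late change, and 115 ribosomal protein genes and 52 subtelomeric genes a lower one. The mating, recombination, telomere and bouquet, G1/S and subtelomeric calls held with an estimated correlation.

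**Figure D3:**
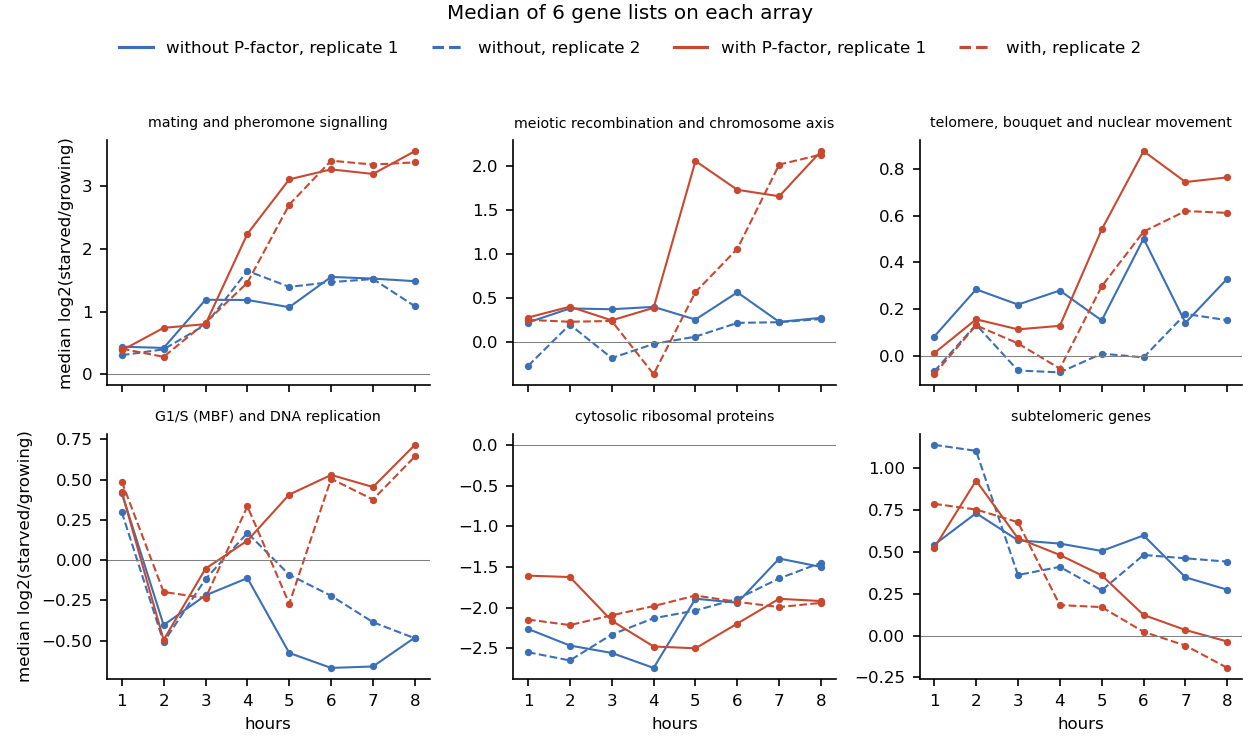
Median log2 ratio of starved over growing cells for 6 gene lists against hours after nitrogen removal, with 1 line for each array series. The mating list reached 3.56 and 3.38 at 8 h with P-factor and 1.49 and 1.09 without, and the subtelomeric list ended at -0.04 and -0.19 with P-factor.

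**Figure D4:**
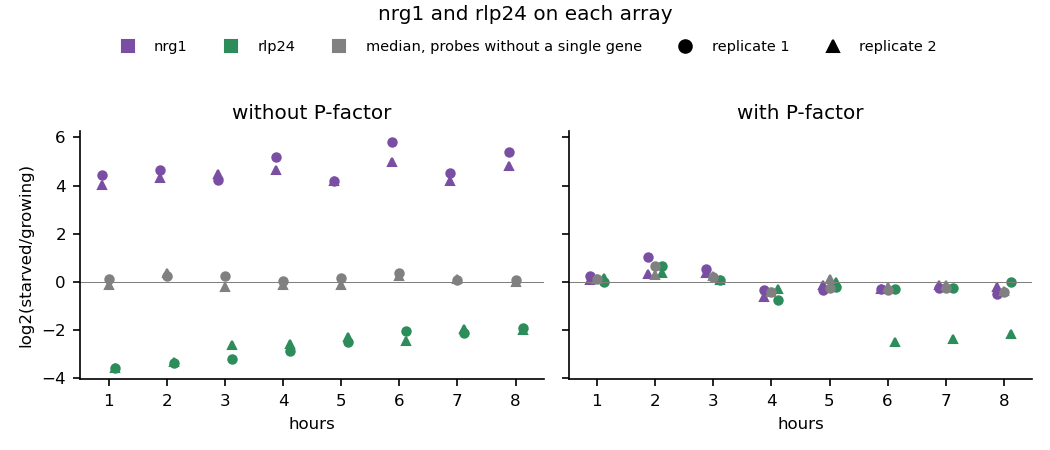
Log2 ratios of nrg1 and rlp24 and the median of probes without a single gene on each array, against hours after nitrogen removal, in the condition without P-factor (left) and with it (right). With P-factor both genes lay near the median of these probes, except rlp24 in replicate 2 at 6, 7 and 8 h (-2.48, -2.35 and -2.15).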

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

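The tests by replicate, the swaps of whole series for the late difference and for the 8 hours, and the tests on rlp24, on the chromosome II genes, on ribosomal protein genes with low signal and on the subtelomeric list and the other lower genes split by their level were chosen only after the results were seen. The change between 1 to 3 h and 6 to 8 h differed between the conditions in 1241 genes, tested by the difference of both changes.

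This late difference may reflect the pheromone, the strain or the arrays. A constant offset between the strains or their reference RNAs cancels in it, but could enter the difference averaged over 1 to 8 h. For the 102 genes higher in that average, the median difference at 1 to 3 h was 0.13 of that at 6 to 8 h (0.25 against 1.85). This argues against an offset for these genes as a group, though 3 of them had an early difference at least 0.8 of the late one. For the 58 lower genes the ratio was 0.64 (-0.76 against -1.20), and 16 of them reached 0.8, which keeps an offset open. For the late difference, an effect of the arrays of 1 replicate alone is argued against by a correlation of 0.712 across genes between the replicate 1 and the replicate 2 arrays. With P-factor the array numbers fell from 1 to 8 h in replicate 1 and rose in replicate 2. Without P-factor they also rose in replicate 2 and followed no steady order in replicate 1. A steady drift with array number would thus largely cancel in the late difference of replicate 2. The correlation of 0.712 over all genes therefore argues against such a drift as the only cause. Of the 1241 called genes, 1240 had the same sign in both replicates. They were called on both replicates together, which favours a shared sign, so this count does not decide the question. In both replicates the conditions had separate array numbers, so other effects of the arrays stay open. The number of strains measured under both treatments was 0, so a strain difference without any role of P-factor cannot be told apart from an effect of the pheromone, which stays open as well.

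For this late difference, the arrays were split into conditions within each hour, on genes measured on all arrays. Each count of splits or pairings given here includes the real one. Of 100 splits, only the real one gave as many as 1175 genes, and the highest other gave 5. These splits take arrays as units and break up the array series, so they cannot exclude chance at the level of the series. Swapping whole series, the units that were repeated, gave 3 pairings, too few for a share under 0.05. Of these 1 gave as many genes as the real 1175 for this difference, with 76 in the highest other. For the average over 1 to 8 h, 2 of 100 splits gave as many as the real one, which called 3.61% of these genes, and the highest other called 7.98% (352 genes). That split took 4, 5, 3 and 4 arrays of the 4 series as P-factor arrays and so followed none of them, and the next highest count was 2. For this average the 3 pairings of series called 3.61% of the genes in the real one and 0.522% (23 genes) in the highest other, again 1 of 3. For the 8 hours tested together, 1 of 100 splits gave as many as the real 335 (highest other 172), and 1 of the 3 pairings of series, with 15 in the highest other. For late minus early, 1 of 100 splits of the 12 arrays gave as many as the real 1654 without P-factor (highest other 750), and 1 of 100 as many as the real 2155 with it (highest other 974).

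In a run of 17 neighbouring genes on chromosome II between pfl5 and gal1, 9 genes, nrg1 among them, read near the median of probes without a single gene on at least 12 P-factor arrays and on at most 4 of the others. Scattered spots without signal are argued against by the fullest window of 11 neighbouring genes, which held 7 such genes, against 1 outside this run and 4 at most after shuffling (permutation p = 1e-04, the smallest the permutations can give). Of the 12 genes of the run away from that level without P-factor, 9 lay near it on at least 12 of the 16 P-factor arrays, which is consistent with a segment missing or silent in the strain CRL672. This explanation stays open because a ratio shows no absolute level and because SPBC8E4.04, prt2 and SPBPB2B2.06C lay near that level on only 10, 9 and 9 arrays. For rlp24, which also lay near this level with P-factor, a difference between the strains stays open, since the 3 P-factor arrays on which it lay more than 1.5 away were all of replicate 2, at 6, 7 and 8 h (-2.48, -2.35 and -2.15).

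The lower late minus early change of ribosomal protein and subtelomeric genes with P-factor might come from scaling, from the arrays of 1 replicate or from spots without signal. For ribosomal protein genes it held both higher early and lower late values. The list median of the difference between the conditions was 0.54, 0.58 and 0.21 at 1, 2 and 3 h. It was -0.13, -0.46 and -0.45 at 6, 7 and 8 h, with no gene of the list called at these hours. For ribosomal protein genes, array centring or scale is argued against by a highest list median of -0.84 under the 3 other scalings (-0.79 as reported), and the arrays of 1 replicate alone by medians of -0.61 and -0.93 within the replicate 2 and the replicate 1 arrays. Of the 109 called genes, 0 lay near the level of probes without a single gene on at least 12 P-factor arrays. The ratios of the list lay far below that level (median -2.05 with P-factor), so this count was nearly given. It shows that these genes did not read like empty spots. It does not test for low intensity, which was not available. Their median correlation with that level, after removing phase means, was 0.4, which does not decide the question. For the subtelomeric genes this correlation was 0.26, with quartiles from -0.09 to 0.63, and 50% of the 42 lower genes lay near the level. Without genes near it the list kept a median of -0.55, which argues against spots without signal as the whole cause. The correlation was 0.67 for the 17 lower genes near the level on at least 12 arrays without P-factor, where such spots remain a candidate explanation. It was 0.01 for the remaining 25 (quartiles -0.20 to 0.30). Of the 17 and the 25, 100% and 16% lay near the level on at least 12 P-factor arrays. The split thus partly set these correlations, which do not decide the question. For the other 338 lower genes the correlation was 0.08, against 0.54 for the probes themselves, which argues against spots without signal for all of them together. Of them 31.4% lay near the level with P-factor, against 13.1% of all genes. For the 107 of them near the level on at least 12 arrays without P-factor it was 0.57, so spots without signal remain a candidate explanation there. For the remaining 231 it was -0.01 (quartiles -0.16 to 0.18). Of the 107 and the 231, 80.4% and 8.7% lay near the level on at least 12 P-factor arrays, so this split does not decide the question either.

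The lists whose median difference passed were M-cell genes (1.53), recombination (1.26), mating (1.18), G1/S and DNA replication (0.78), telomere and bouquet (0.59), proteasome (0.29), amino acid biosynthesis (-0.18), glycolysis (-0.41), nitrogen uptake (-0.48), subtelomeric genes (-0.63) and ribosomal proteins (-0.79). With an estimated correlation the calls of M-cell, proteasome, amino acid, glycolysis, nitrogen uptake and ribosomal protein genes were lost (adjusted p = 0.0567, 0.171, 0.668, 0.478, 0.338 and 0.106). The genes with a higher late change with P-factor were shk2 (5.49), mam3 (5.22), dni2 (5.04), dni1 (4.73), mug14 (4.08), meu13 (3.88), mug8 (3.44), cig2 (3.30), rec8 (3.30), num1 (3.26), hop1 (2.82), mek1 (2.75), mik1 (2.71), bqt1 (2.66), tht1 (2.60), crs1 (2.30), rep1 (2.28), cdt2 (2.19), pat1 (2.13), mat1-Mi (1.94), mat1-Mc (1.87), ser3 (1.86), mam2 (1.83), dhc1 (1.69), map3 (1.41), ste11 (1.03), kms1 (0.89), mei4 (0.88), bqt2 (0.86) and pup3 (0.79). Those with a lower one were rlp24 (-2.68), SPAPB1A11.03 (-2.26), SPAC869.01 (-2.25), hsp3105 (-2.14), SPAC186.02C (-2.10), SPAC11D3.01C (-2.08), hry1 (-1.99), dak2 (-1.92), rps2201 (-1.51), rps2202 (-1.32), put4 (-1.21), lys9 (-1.10), pyk1 (-0.98) and sxa2 (-0.53). Among probes outside the comparisons of genes, 49.8% of 319 were lower and 3.8% higher in the same difference, 53.6% in all against 26.2% of genes.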

How the results depend on the processing

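The settings with all probes, without genes near the level of probes without a single gene, and centred outside the ribosomal protein list were chosen after the data were seen. No count of genes over several hours left the range of 1.5 times its reported value with the values as deposited, with scaled arrays, with either filter on missing values, with the robust spread, with all probes or with centring outside the ribosomal protein list. Nor did the late minus early counts with the fixed block or the linear trend, which were run for these alone. Of the counts at single hours, that at 1 h became 4 with scaled arrays, that at 2 h became 5 with genes measured on all arrays or with the robust spread, and those at 2 and 3 h became 6 and 3 with all probes, and that at 4 h became 2 without the block. Without the genes near the level of probes without a single gene, limma called 0 genes at 1, 2 and 3 h (194, 207 and 207 at an unadjusted p below 0.05), 1 at 4 h and 31 at 5 h. With at least 1 on the log2 scale required, which selects fewer of the same calls, the counts were 1396 and 1372 for starvation without and with P-factor, 78 for the averaged P-factor difference, and 361, 623 and 376 for late minus early without P-factor, with it and their difference. Without the block, the averaged P-factor difference had 1457 genes and the difference of late minus early changes 683. Averaging each series first left 23 genes in the averaged difference, with 4 series means in the fit. Within the replicate 2 arrays of both conditions, with the hour as block, the averaged difference had 769 genes and the late minus early difference 537, and within the replicate 1 arrays the averaged difference had 2204. Without the genes near the level of probes without a single gene, the averaged difference had 85. The cause of the changes without the block and within either replicate was not tested. The requirement on size does not apply to the tests that take all hours together, and within 1 replicate single hours leave no residual degrees of freedom.

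Leaving out 1 array series gave 3099 to 3291 genes for starvation without P-factor, 2329 to 3657 with it, 20 to 1194 for the averaged difference, 118 to 427 for the hours of that difference together, 2951 to 3580 for the hours against growth, 1024 to 2020 and 1805 to 2426 for late minus early without and with P-factor, and 562 to 967 for their difference. These fits leave 1 array in each group of the condition, assumed to vary like the others. Leaving out 1 array gave 3228 to 3335, 3136 to 3223, 120 to 191, 260 to 412, 3692 to 3822, 1779 to 2082, 2342 to 2586 and 1076 to 1266 in the same order. The list shift of telomere, bouquet and nuclear movement in the averaged difference ended without the genes near the level of probes without a single gene, with a median of 0.02 (adjusted p = 0.996), slightly below the other genes in rank. Over all pairs of a list result and an alternative, the call was lost in 45 and gained in 35. Within the replicate 1 arrays the M-cell, recombination, proteasome, ribosome biogenesis, subtelomeric and telomere and bouquet lists lost theirs in the averaged difference and glycolysis in the difference of late minus early changes, as amino acid genes did there within the replicate 2 arrays. Without the genes near the level of probes without a single gene, calls were lost for histones in starvation without P-factor, recombination and mitosis genes in starvation with it, proteasome and subtelomeric genes in the averaged difference, and proteasome genes in the difference of late minus early changes. The calls lost without 1 series were histones, mitosis and amino acid genes in starvation without P-factor, and mitosis genes in starvation with it. In the averaged difference they were proteasome, ribosome biogenesis and telomere and bouquet genes. In late minus early they were G1/S and mitosis genes without P-factor and G1/S, stress and nitrogen uptake genes with it. In the difference of both they were amino acid, glycolysis, nitrogen uptake and proteasome genes. Of the named genes called in the difference of late minus early changes, 36 of 83 were called in every alternative, 14 were lost without 1 array and 41 without 1 series, and in the averaged difference these numbers were 9 of 32, 4 and 22. No named gene called in a reported comparison changed its sign there in the alternatives run. Named genes that were not called were not checked for such a turn. Signal over background was not available here, and 977 genes without P-factor and 631 with it lay within 0.5 of the median of probes without a single gene on at least 12 of 16 arrays.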

Other observations

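The tests on meu and mug genes and on the groups of genes they concern were chosen after the results were seen, and those on neighbouring genes before. The uracil breakdown gene urg1 stood at 6.07 ± 0.25 over growth without P-factor on average and fell late by 2.36, and with P-factor it stood at 6.59 ± 0.26 and fell late by 2.93, next to urh1, which fell by 3.20. Between 1 to 3 h and 6 to 8 h the conditions shared 736 higher and 438 lower genes, where 389.0 and 174.5 would be shared if calls were independent, and 11.5% of the genes called in both were called in opposite directions. Core stress genes fell late with P-factor in 11 of 22 cases and rose in 3 (median -0.58, adjusted p = 0.0109, and adjusted p = 0.346 with an estimated correlation), such as cta3 by -2.12 ± 0.20. Their median was 0.02 in replicate 1 and -1.20 in replicate 2, and the call was lost without replicate 2. With P-factor nitrogen uptake genes fell in 10 of 19 cases and rose in 4 (median -0.45, adjusted p = 0.0121, and adjusted p = 0.346 with an estimated correlation), such as gdh1 by -2.37 ± 0.26, a call lost for the list without replicate 1 and with scaled arrays.

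Sporulation genes split with P-factor, where late minus early 7 of 17 rose and 7 fell (median -0.05, adjusted p = 0.896). Among those that rose were spo5 at 1.80 ± 0.23, isp3 at 1.63 ± 0.28 and mde10 at 1.56 ± 0.17. The M-factor and receptor genes were already high at 1 h in replicate 1 of the P-factor condition, with 3.66 for mfm1 and 2.97 for mam2 against 0.75 and 0.47 in replicate 2.

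The hypothesis that neighbouring genes change together was tested by shuffling the gene order. Of the 489 genes with a lower late change with P-factor, 77 adjacent pairs were found, against a mean of 49.3 after shuffling (permutation p = 1e-04, the smallest the permutations can give), and without the subtelomeric list 60 pairs against 41.2 (permutation p = 0.001). Genes with a higher late change formed 24.5 more adjacent pairs than the mean of 116.5 after shuffling (permutation p = 0.005). Both results went with the hypothesis, and whether shared control or shared spot neighbourhoods on the array stand behind it was not tested.

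Genes named meu or mug, after their rise in meiosis in other work, might have a higher late change with P-factor more often than other genes. Of 109 such genes, 25 had one (22.9%, against 15.5% of the other 4702), with an odds ratio of 1.63 (one-sided Fisher's exact test, p = 0.0274). Of the same genes, 24 had a lower late change (22%, against 9.9% of the others), with an odds ratio of 2.57 (one-sided Fisher's exact test, p = 0.000178). Of these 24, 16 lay near the level of probes without a single gene on at least 12 arrays without P-factor. Such genes were thus overrepresented in both directions, and the odds ratios were not compared by a test. Of the 465 other lower genes, 108 lay near that level.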
